A study of Homo sapiens with 26 samples.

How the data were processed

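Bone marrow of patients with myelodysplastic syndromes (MDS) was profiled before canakinumab or during cycles of it. MDS are clonal disorders in which the marrow makes too few mature blood cells. Canakinumab is an antibody that neutralises interleukin-1 beta. Per the labels, live mononuclear cells (MNC) or lineage-negative CD34+ cells, the latter called CD34+ libraries here, were purified by flow sorting, loaded on a 10x Genomics Chromium chip and sequenced on an Illumina instrument. Per the submitters' processing notes, the authors used Cell Ranger with the human build GRCh38 (hg38), and the Cell Ranger version is not given in the sources used here. The deposited matrices hold raw UMI counts (unique molecules) per gene and cell barcode for 33538 genes in each of 26 libraries, and no barcode has fewer than 500 UMIs. Gene coordinates came from the GENCODE annotation of the same build, and no genome sequence was used here.

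The labels gave 6 groups. Libraries labelled as baseline or pre-canakinumab are called untreated here, which says nothing about other treatment. There were 5 untreated, 5 cycle 2 and 5 later-cycle MNC libraries, and 3 untreated, 3 cycle 2 and 5 later-cycle CD34+ libraries. The later libraries come from cycles 4, 5, 8, 11 and 14, with 1 library of each cell fraction per cycle, and were taken as 1 group. Replicate numbers follow the order of deposition and only name a library. The deposited records form 3 consecutive runs, called deposit blocks. Block 1 holds all later libraries with 1 untreated and 1 cycle 2 library of each fraction, and blocks 2 and 3 hold untreated and cycle 2 libraries alone. Donors are not given in the labels, so no libraries were paired across treatment groups. P-values measure the spread between these libraries, some of which may share a donor. For genes, edgeR takes part of that spread from other genes.

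Cells were kept with at least 500 UMIs, at least 250 detected genes and at most 15% of UMIs from mitochondrially encoded genes. Scrublet, run in scanpy 1.11.5, scored doublets per library. Its automatic threshold marked 0 to 12.3% of the cells that passed these limits, with a median of 0.22%. The highest scores were therefore removed up to 0.8% per 1000 barcodes, a rule set after those results were seen. It marked 1.13 to 6.83% of the passing cells per library. Of 111939 barcodes, 31970 exceeded the mitochondrial limit, 3556 were removed as doublets and 75474 cells were kept. MNC and CD34+ cells were clustered apart on log-normalised counts, 2000 variable genes and 30 principal components, with 3 neighbours taken from each library and the nearest 25 kept, by the Leiden method at resolution 1 (igraph 0.11.9, leidenalg 0.10.2). Immunoglobulin, T cell receptor, HLA, mitochondrial, ribosomal protein, XIST and Y-linked genes took no part in clustering. A cluster was named "X-like" where at least 3 markers of a fixed class list, each at a log2 fold of at least 1 over the other cells, were among its top 50 genes and its leading genes did not go against the name. Clusters with a median under 1000 UMIs were left unnamed, a threshold set after the clusters were seen, and their share is given per group. No pair of libraries agreed within sampling noise, the lowest chi-square per degree of freedom being 5.35.

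Counts were summed per library, over all kept cells or over the cells of a class where a library had at least 20. The sums were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test, with TMM scaling, the default expression filter, the deposit block as an additive covariate and Benjamini-Hochberg adjustment at 0.05. The 12 gene comparisons were cycle 2 against untreated and later cycles against untreated over all cells of each fraction, and cycle 2 against untreated within monocyte-like, T-like, cytotoxic T/NK-like, B-like and erythroid-like MNC and within HSPC-like (hematopoietic stem and progenitor), erythroid progenitor-like and myeloid progenitor-like CD34+ cells. XIST, TSIX and Y-linked genes were left out of every test. CPM values are the summed counts of a library scaled to a common total, given as mean ± SD, and log2 fold changes are given ± SE. Adjusted p-values of genes are from edgeR's quasi-likelihood test throughout, and DESeq2 1.42.0 was the other gene test.

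A set of 26 gene lists was tested in each comparison with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with the correlation estimated from the libraries and with fry. Lists with at least 5 measured genes were tested. The lists covered NF-kB and TNF response, IL-1 pathway and inflammasome, type I interferon response, interferon gamma response, MHC class II, IL-6 and STAT3 response, immediate early and handling stress, myeloid alarmins, hemoglobins and red cell proteins, heme synthesis and iron, erythroid transcription factors and signalling, myeloid transcription and granule genes, stem cell genes, S phase, G2 and M phase, ribosomal proteins, oxidative phosphorylation, glycolysis and hypoxia, p53 and apoptosis, unfolded protein response, cytotoxic effector genes, T cell naive and memory genes, T cell inhibitory receptors, TGF-beta response, platelet genes and plasma cell genes.

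The genes named were set by rule. In each comparison they were up to 10 genes that rose and 10 that fell with the greatest fold change among genes past the threshold with an average log2 CPM of at least 4 and the same sign in each deposit block holding both groups, up to 6 members of a called list that passed the threshold, and 18 fixed genes whatever their p. Members of called lists with small unadjusted p that stand in the text as examples were chosen after their values were seen. Immunoglobulin, T cell receptor and mitochondrial genes are not named. Some genes that the rule would name are not reported. The 3' tags of near-identical genes such as HBA1 and HBA2, HSPA1A and HSPA1B, or CCL4 and CCL4L2 may be exchanged between them, so their separate values are uncertain.

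Class shares are percentages of a library's kept cells. Cycle 2 and untreated shares were compared by exact permutation tests and, within block 1, shares were related to the cycle number over 7 libraries by Pearson's r and Spearman's rho with exact permutation p, all two-sided. The sort was checked by the CD34 transcript with a pseudocount of 1 CPM. Intervals on shares are exact 95% binomial intervals and cover counting error only. The groups, tests, covariates, lists, class markers, naming rule and the first set of alternatives were fixed before the data were examined.

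The procedure was tested on data simulated from each comparison's means, library sizes and spread, with 100 genes changed 2-fold and 100 changed 4-fold. For cycle 2 over all MNC (17485 genes), 3% of 2-fold and 50% of 4-fold changes were recovered, and for later cycles (18420 genes) 0% and 4%. For cycle 2 over all CD34+ cells (15878 genes) 0% of either size was recovered, and for later cycles (16656 genes) 17% and 68%. Within classes, recovery of 2-fold and 4-fold changes was 30% and 85% in monocyte-like cells (8843 genes), 33% and 89% in T-like cells (10638 genes), 67% and 91% in cytotoxic T/NK-like cells (11861 genes), 57% and 92% in B-like cells (10254 genes), and 12% and 78% in erythroid-like cells (9476 genes). In CD34+ classes it was 8% and 61% in HSPC-like cells (12575 genes), 72% and 99% in erythroid progenitor-like cells (11215 genes), and 56% and 94% in myeloid progenitor-like cells (9871 genes). Of simulated calls 1.85% to 9.15% were false, except 11.5% for later CD34+ cells, 18.8% in HSPC-like cells and 1 of 5 for later MNC, and over all CD34+ cells at cycle 2 there were 0 calls. Of 25 unchanged lists 0 were called in any comparison, and the changed list was called in each. Genes were simulated independently of each other and the unchanged lists were random genes. So this result does not measure false calls of lists whose members vary together.

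The alternatives tried were no deposit block, size factors of the RLE kind, no expression filter, DESeq2, doublets kept, at least 1000 UMIs per cell, Leiden resolution 2, each library left out in turn, other denominators and tests for shares, a pseudocount of 10 CPM for the sort check, and an estimated correlation or fry for lists. Added after seeing the data were a mitochondrial limit of 30%, leaving out the libraries with the most cells over the limit, shares of named cells, class comparisons at later cycles, and a test of the difference between MNC and CD34+ changes.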

Results

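Gene expression was measured in single bone marrow cells of patients with MDS. Marrow during canakinumab was compared with marrow before canakinumab, called untreated. Live mononuclear cells were measured, and the CD34+ fraction that holds stem and progenitor cells. There were 5 untreated, 5 cycle 2 and 5 later-cycle MNC libraries, and 3 untreated, 3 cycle 2 and 5 later-cycle CD34+ libraries. A library held 17630982 to 61499985 UMIs. The median kept cell had 1066 to 6010 UMIs in MNC libraries and 11436.5 to 34667 in CD34+ libraries. In the CD34+ fraction 295 to 2018 cells per library were kept. More than 50% of barcodes exceeded the mitochondrial limit in 5 libraries. These were replicate 3 of the untreated CD34+ (88.5%), cycle 2 CD34+ (71.3%), untreated MNC (61.0%) and cycle 2 MNC (51.5%) groups, and replicate 2 of the cycle 2 CD34+ group (50.2%).

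CD34, the surface antigen of the CD34+ sort, stood at 83.5 ± 32.9 CPM in CD34+ and 5.74 ± 3.97 CPM in MNC libraries of the same 11 marrows. The mean log2 ratio was 3.83 ± 1.18 (SD, n = 11), higher in 11 of 11 marrows (exact permutation p = 0.000977, the smallest this design allows).

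The make-up of the mononuclear fraction varied widely between libraries of each group, and 0 of 11 cell classes differed between cycle 2 and untreated. Cytotoxic T/NK-like cells formed 32.2% ± 8.13 of untreated and 26.3% ± 16.2 of cycle 2 MNC. T-like cells formed 22.1% ± 10.1 and 16.2% ± 8.65, and B-like cells 13.6% ± 13.1 and 16% ± 15 (SD, n = 5 each). Monocyte-like cells, the main source of IL-1 beta in marrow, formed 8.53% ± 8.64 and 3.78% ± 3.34. Theirs was the smallest p (exact permutation p = 0.286 at n = 5, two-sided, adjusted p = 0.865, smallest possible 0.00794). Erythroid-like cells formed 5.35% ± 5.50 and 8.17% ± 8.36, erythroid progenitor-like cells 4.23% ± 4.31 and 2.34% ± 2.31. HSPC-like cells formed 4.48% ± 7.31 and 3.38% ± 4.75. Myeloid progenitor-like, plasma-like, megakaryocyte/platelet-like and basophil/mast-like cells each formed under 2% in both groups. Clusters left unnamed for their low UMIs held 5.35% ± 4.43 of untreated, 19.7% ± 27.7 of cycle 2 and 7.48% ± 2.38 of later MNC. In cycle 2 replicate 5 they held 66.2%. The unnamed cluster with markers nearest to monocytes held 0.840% ± 0.737 of untreated and 9.38% ± 15.2 of cycle 2 MNC, and 36.2% in the highest library. That nearest to erythroid progenitors held 4.51% ± 4.62 and 10.3% ± 12.9. So the order of the groups in the monocyte-like and erythroid progenitor-like shares depends on leaving these clusters unnamed.

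In the CD34+ fraction, HSPC-like cells had the highest mean share, at 49.8% ± 34.4 of untreated and 46.0% ± 35.2 of cycle 2 cells (SD, n = 3 each). Replicate 3 carries these means, at 82.4% and 86.2%, where the other libraries had 13.9% and 53.3% untreated and 21.2% and 30.5% at cycle 2. In untreated replicate 2 erythroid-like cells (19.1%) exceeded HSPC-like cells. Myeloid progenitor-like cells formed 3.95% ± 4.09 and 8.80% ± 9.02. Erythroid-like cells formed 10.4% ± 9.66 and 6.36% ± 6.80, and erythroid progenitor-like cells 7.32% ± 5.46 and 6.70% ± 5.84. Megakaryocyte/platelet-like cells formed 7.58% ± 2.19 and 6.16% ± 3.37, and basophil/mast-like cells 5.17% ± 2.01 and 7.85% ± 3.46. The smallest exact permutation p was 0.3 at n = 3, and 3 libraries against 3 cannot go below 0.1. Unnamed clusters held 15.7% ± 17.3 of untreated, 18.2% ± 14.3 of cycle 2 and 20.3% ± 5.36 of later CD34+ cells. An edgeR quasi-likelihood test on cell numbers with the deposit block gave adjusted p of at least 0.946 in CD34+ and 0.953 in MNC libraries.

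**Figure D1:**
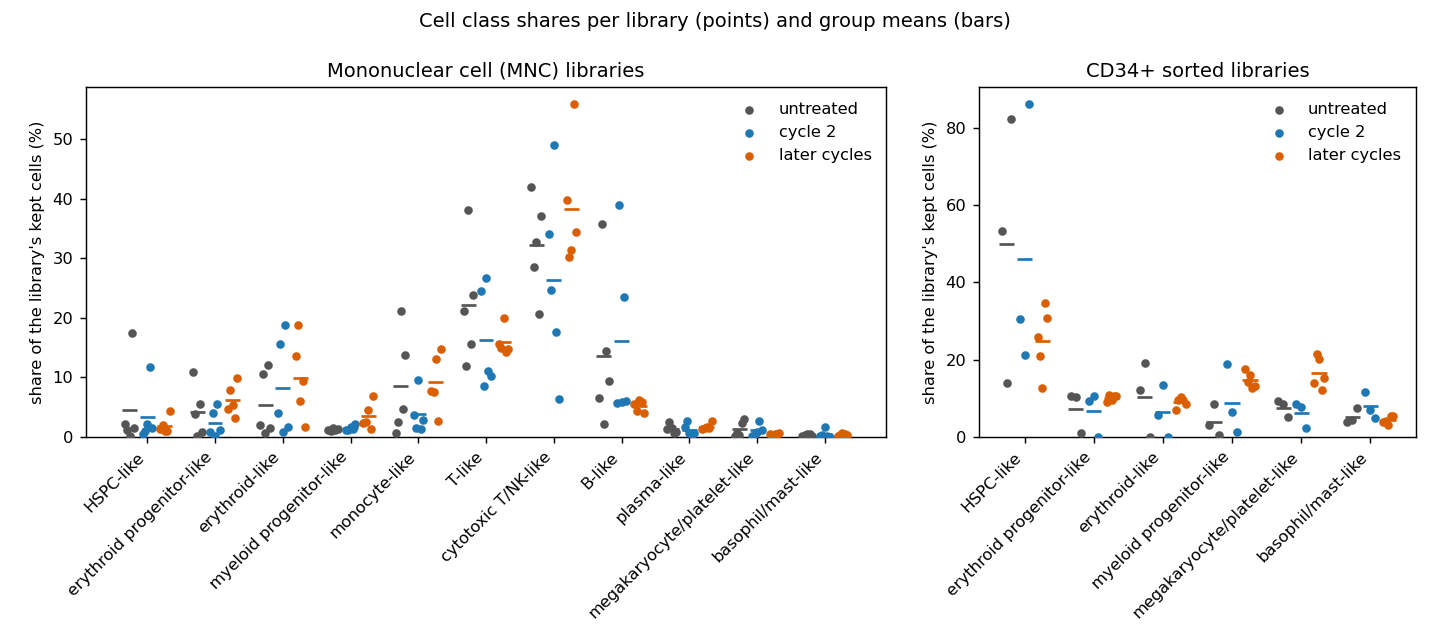
Share of each library's kept cells (%, vertical axis) in each named cell class (horizontal axis), with MNC libraries on the left and CD34+ libraries on the right. Each point is a library, coloured by group, and each bar is a group mean, such as 8.53% of monocyte-like cells in untreated and 3.78% in cycle 2 MNC.

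Over all mononuclear cells, genes of inflammatory signalling and of the early stress response were lower at cycle 2 than in untreated marrow, by small amounts. Of 24 measured NF-kB and TNF response genes 17 were lower, with a median log2 change of -0.26 (camera adjusted p = 0.000983, and adjusted p = 0.345 with an estimated correlation). The chemokine gene CCL3 stood at -0.93 ± 0.48, from 32.8 ± 18.6 to 19.0 ± 10.5 CPM (n = 5 each). NFKB1, which encodes a subunit of NF-kB itself, stood at -0.27 ± 0.14. Of 20 immediate early and handling stress genes 16 were lower, median -0.18 (camera adjusted p = 3.16e-06, and adjusted p = 0.287 with an estimated correlation). Among them were IER2 at -0.57 ± 0.22, NR4A1 at -0.80 ± 0.31, FOS at -0.79 ± 0.36 and the phosphatase gene DUSP1 at -0.51 ± 0.28. Type I interferon response genes were lower in 23 of 25, median -0.25 (camera adjusted p = 3.16e-06, and adjusted p = 0.596 with an estimated correlation). Among them were IFI44 at -0.41 ± 0.16 and HERC5 at -0.35 ± 0.15.

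Also called lower in all mononuclear cells at cycle 2 was interferon gamma response (18 of 20 genes, median -0.16). Lists of cell metabolism called lower were oxidative phosphorylation (21 of 21, -0.16) and glycolysis and hypoxia (16 of 20, -0.23, with the lactate dehydrogenase gene LDHA at -0.42 ± 0.18). Lists of cell stress called lower were p53 and apoptosis (15 of 20, -0.08, with CDKN1A at -1.06 ± 0.63) and unfolded protein response (16 of 20, -0.13, with DDIT3 at -0.39 ± 0.17). Hemoglobins and red cell proteins were called higher (20 of 20, median 0.40), with HBB at 0.82 ± 0.86 and the alpha-globin gene HBA1 at 1.01 ± 0.91. So was MHC class II, which presents antigen to helper T cells (11 of 12, 0.18, with its transcriptional activator CIITA at 0.40 ± 0.21). For these 7 lists the camera adjusted p were at most 0.0301. With an estimated correlation their adjusted p were 0.287 to 0.883. Among the fixed genes, IL1B, the target of the antibody, stood at 13.1 ± 10.9 CPM untreated and 8.23 ± 5.03 at cycle 2 (log2 change -0.57 ± 0.61). CXCL8, which encodes the neutrophil chemokine interleukin-8, stood at -1.04 ± 0.87, and TNF at -0.58 ± 0.38. The calprotectin genes S100A8 and S100A9 stood at -0.94 ± 1.47 and -0.89 ± 1.68. Red cell genes GATA1 (0.14 ± 0.87), KLF1 (0.13 ± 1.0), EPOR (0.11 ± 0.82) and TFRC (0.11 ± 0.84) moved by less than their errors. So did the IL-1 receptor genes IL1R1 (0.04 ± 0.77), IL1R2 (-0.86 ± 1.07) and IL1RAP (0.04 ± 0.39). The edgeR quasi-likelihood test called 0 of 17485 genes (68 at an unadjusted p under 0.05, and 0 by DESeq2). Of the list members 0 passed adjusted over the list alone.

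Monocyte-like cells at cycle 2 showed lower NF-kB and TNF response genes, 21 of 22 with a median log2 change of -0.44 (camera adjusted p = 1.74e-07, and adjusted p = 0.365 with an estimated correlation). CXCL8 went from 185 ± 256 to 32.6 ± 34.8 CPM (-2.28 ± 0.91). Untreated replicates 1 and 2 stood at 581 and 309 CPM, and replicate 1 had 22 monocyte-like cells. The other untreated libraries stood at 5.41 to 16.6 and the cycle 2 libraries at 3.34 to 87.7 CPM, so the groups overlap. CCL3 went from 71.4 ± 101 to 19.9 ± 20.6 CPM (-1.53 ± 0.57), and IL1B from 90.2 ± 83.0 to 42.9 ± 43.2 CPM (-1.40 ± 0.87). CCL4 stood at -0.97 ± 0.51 and the adhesion gene ICAM1 at -0.53 ± 0.30. NFKBIA, which encodes the inhibitor that holds NF-kB in the cytoplasm, stood at -0.48 ± 0.30, and the inflammasome sensor gene NLRP3 at -0.15 ± 0.30. Immediate early genes were lower in 16 of 20, median -0.29, with JUN at -1.23 ± 0.50 and SOCS3, a feedback inhibitor of cytokine signalling, at -0.52 ± 0.27. Of MHC class II genes 10 of 11 were higher, median 0.25, with HLA-DPA1 at 0.43 ± 0.21. These 2 lists were called (camera adjusted p = 0.000102 and 0.00196, and adjusted p = 0.365 and 0.548 with an estimated correlation). The alarmin genes S100A8 and S100A9, at 13420 ± 4509 and 10270 ± 6589 CPM untreated, stood at -0.27 ± 0.30 and -0.29 ± 0.56. Lists of other cell types were also called in these cells. The cytotoxic effector list was lower in 10 of 12 (median -0.31, with the granulysin gene GNLY from 189 ± 140 to 74.9 ± 50.9 CPM). The plasma cell list was lower in 6 of 7 (median -0.80, with 3 immunoglobulin genes passing adjusted over the list alone). Their camera adjusted p were 1.87e-05 and 7.84e-06, and adjusted p were 0.523 and 0.308 with an estimated correlation. The edgeR test called 0 of 8843 genes (64 unadjusted, and 0 by DESeq2).

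Lymphocytes also showed lower immediate early genes at cycle 2. In T-like cells 15 of 19 were lower (median -0.30) with IER2 at -0.72 ± 0.27, JUN at -0.88 ± 0.34 and FOS at -1.04 ± 0.48. In B-like cells 18 of 20 were lower (median -0.38) with FOS at -1.62 ± 0.56, EGR1 at -1.46 ± 0.51 and IER2 at -1.10 ± 0.39. In cytotoxic T/NK-like cells 17 of 20 were lower (median -0.21) with KLF6 at -0.28 ± 0.12 and NR4A1 at -1.11 ± 0.57. In B-like cells FOS stood at 204 and 308 CPM in untreated replicates 1 and 2. The other untreated libraries stood at 6.76 to 111 and the cycle 2 libraries at 8.60 to 126 CPM, so the groups overlap. The NF-kB list was lower in T-like cells (15 of 18, median -0.15) and in B-like cells (14 of 16, median -0.42). The cytokine gene TNF went from 17.0 ± 7.99 to 8.08 ± 4.77 CPM in T-like cells (-1.08 ± 0.30) and from 10.4 ± 6.86 to 4.50 ± 1.67 CPM in B-like cells (-0.96 ± 0.30), each below the untreated mean in 5 of 5 libraries. NFKBIA stood at -0.88 ± 0.38 in T-like cells, and NFKB1 at -0.50 ± 0.19 and CCL3 at -2.08 ± 0.67 in B-like cells. In T-like cells NFKBIA spanned 49.2 to 395 CPM in untreated and 88.7 to 124 CPM in cycle 2 libraries, so these groups overlap too. These 5 list calls had camera adjusted p of at most 0.0154, and adjusted p of 0.611 to 0.943 with an estimated correlation. The CPM summed over the NF-kB and immediate early lists was lower on average at cycle 2 in deposit blocks 1 and 2, but not in block 3. There it was 5085 and 2250 in untreated and 4085 and 4032 in cycle 2 libraries for T-like cells. For B-like cells it was 3892 and 2401 untreated, and 3536 and 3696 at cycle 2.

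In cytotoxic T/NK-like cells the interferon gamma gene IFNG, itself an effector product, stood at 42.1 ± 20 CPM untreated and 19.5 ± 9.82 at cycle 2 (-1.07 ± 0.23, below the untreated mean in 5 of 5). It was the 1 member of the cytotoxic effector list to pass adjusted over the list alone, and 17 of the list's 20 members were lower (median -0.08, camera adjusted p = 0.0417, and adjusted p = 0.847 with an estimated correlation). Type I interferon response genes were lower in T-like (21 of 25, median -0.14), cytotoxic T/NK-like (22 of 25, -0.18, with OASL at -0.37 ± 0.13) and B-like cells (23 of 24, -0.20, with IFI6 at -0.45 ± 0.16). Oxidative phosphorylation genes were lower in T-like (19 of 21, -0.17) and cytotoxic T/NK-like cells (20 of 21, -0.11). T-like cells also had lower p53 and apoptosis genes (14 of 17, -0.20, with PMAIP1 at -0.81 ± 0.42) and ribosomal protein genes (25 of 25, -0.14). In B-like cells 23 of 25 ribosomal protein genes (0.14) and 15 of 16 cytotoxic effector genes (0.83, with GNLY at 0.79 ± 0.36) were higher, the latter a list of other cell types. Camera gave these 9 lists adjusted p of at most 0.0332. Adjusted p with an estimated correlation were 0.742 to 0.943. By edgeR, 0 genes were called of 10638 in T-like cells (88 unadjusted), of 11861 in cytotoxic T/NK-like cells (273 unadjusted) and of 10254 in B-like cells (126 unadjusted). DESeq2 also called 0 in each.

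Erythroid-like cells of the mononuclear fraction had lower immediate early genes at cycle 2, 14 of 18 with a median of -0.14. FOS went from 38.6 ± 15.5 to 14.1 ± 4.33 CPM (-1.39 ± 0.25) and DUSP1 from 34.1 ± 8.22 to 19.0 ± 3.67 CPM (-0.85 ± 0.24). FOS alone passed adjusted over the list alone. NF-kB genes were lower in 7 of 9 (median -0.38) and ribosomal protein genes in 24 of 25 (-0.19). Plasma cell genes, a list of another cell type, were higher in 9 of 9 (0.60, with JCHAIN from 1.96 ± 1.17 to 126 ± 234 CPM). The cycle 2 values of JCHAIN vary by more than their mean. These 4 lists had camera adjusted p of at most 0.0210. Their adjusted p were 0.318 to 0.993 with an estimated correlation. The globin gene HBB (0.43 ± 0.70) and the erythroid regulators GATA1 (-0.13 ± 0.22) and KLF1 (-0.09 ± 0.27) moved by less than their errors. So did the erythropoietin receptor gene EPOR (-0.13 ± 0.20) and the transferrin receptor gene TFRC (-0.24 ± 0.46). Of 9476 genes edgeR called 0 (33 unadjusted), and DESeq2 called 1, FOS.

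**Figure D2:**
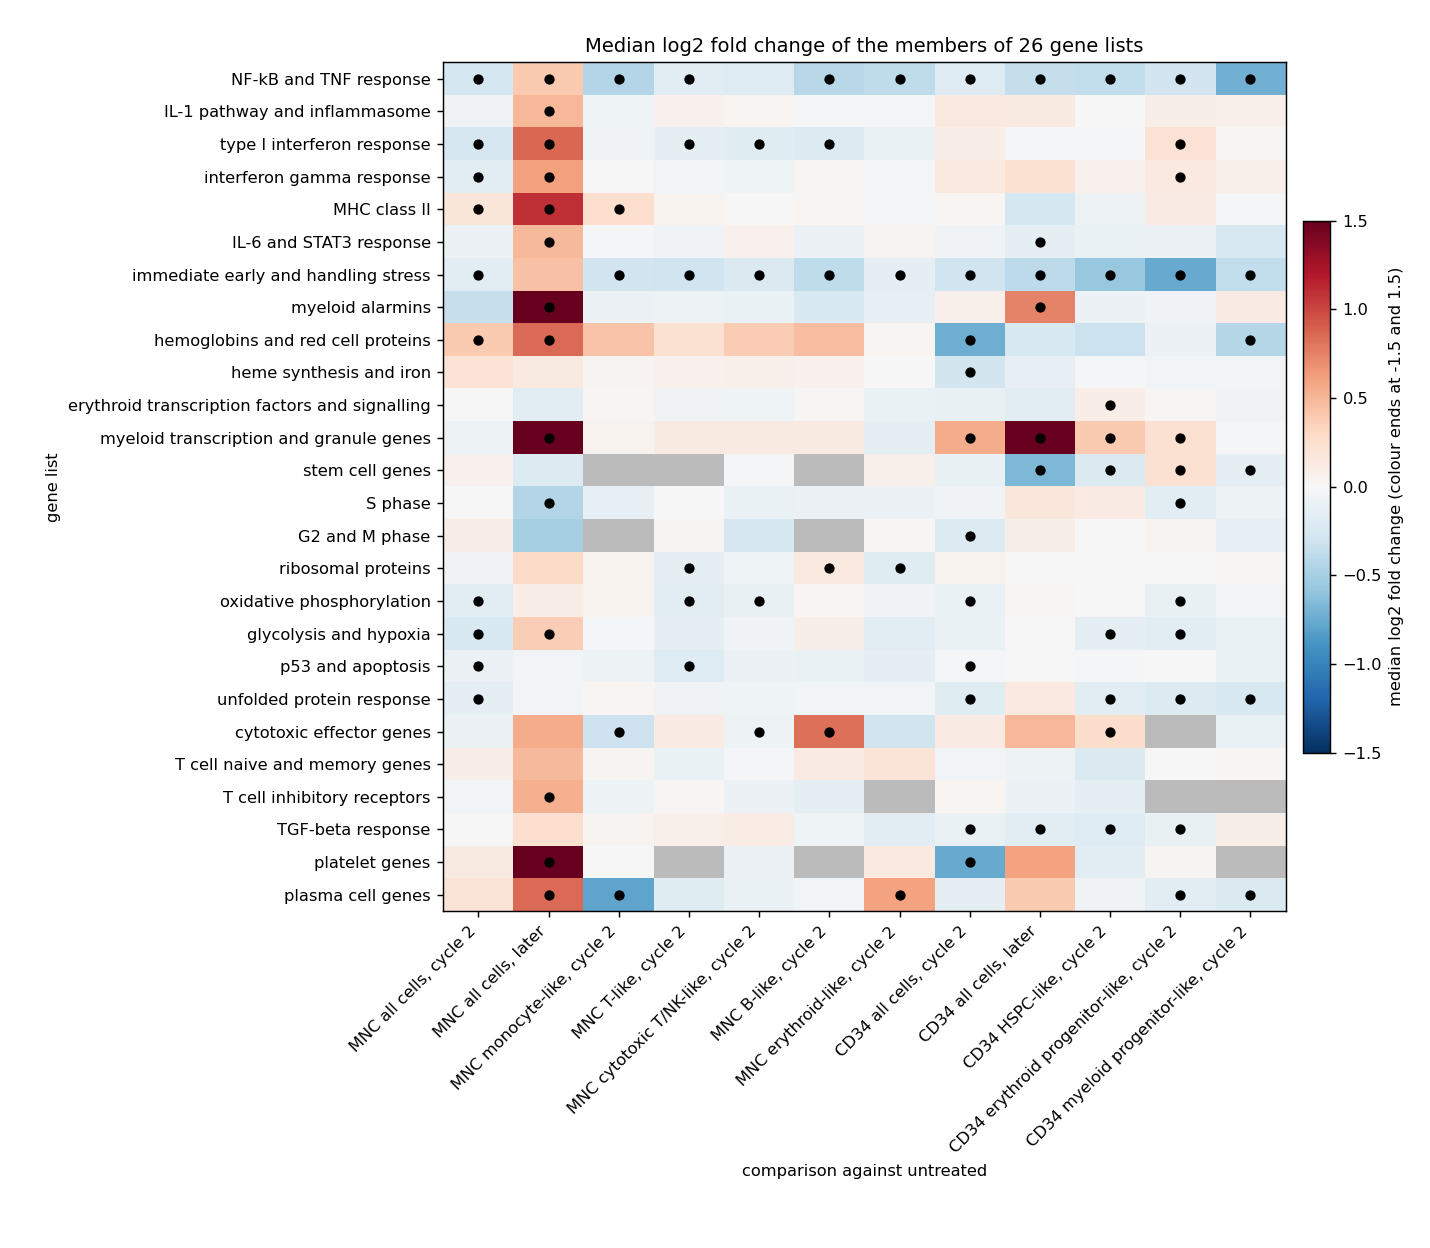
Median log2 fold change (colour, blue lower and red higher than untreated) of the members of each of the 26 gene lists (vertical axis) in the 12 comparisons (horizontal axis), with grey where under 5 members were measured. Black dots mark the 93 calls by camera at the preset correlation. With an estimated correlation 2 held, NF-kB and TNF response in HSPC-like cells at cycle 2 and platelet genes in MNC at later cycles.

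In the CD34+ fraction at cycle 2, NF-kB, immediate early and TGF-beta response genes were lower, and myeloid genes were higher. With an estimated correlation 0 of these 4 list calls held (adjusted p = 0.173 to 0.485). NFKBIA went from 168 ± 79.8 to 95.5 ± 37.8 CPM (-0.76 ± 0.15, n = 3 each, below the untreated mean in 3 of 3). The chemokine gene CXCL2 went from 21.5 ± 12.3 to 6.96 ± 1.47 CPM (-1.51 ± 0.24, 3 of 3). They were the 2 members of the NF-kB list that passed adjusted over the list alone. The list was lower in 20 of 23 genes (median -0.19, camera adjusted p = 9.11e-09, and adjusted p = 0.173 with an estimated correlation). Immediate early genes were lower in 17 of 20 (median -0.30). JUNB stood at -0.96 ± 0.26, ZFP36, which destabilises cytokine transcripts, at -0.61 ± 0.17 and JUN at -0.74 ± 0.24. Of 20 TGF-beta response genes 14 were lower (median -0.10). ID1, an inhibitor of differentiation factors, went from 43.1 ± 27.7 to 9.09 ± 1.93 CPM (-2.25 ± 0.57). Myeloid transcription and granule genes were higher in 19 of 20 (median 0.56), with the granulocyte regulator CEBPA from 26.5 ± 6.81 to 42 ± 3.23 CPM (0.70 ± 0.18) and SPI1 at 0.42 ± 0.24.

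Lists of mature cells were lower in all CD34+ cells. Platelet genes were lower in 14 of 14 (median -0.75, with the platelet chemokine genes PPBP at -4.44 ± 1.60 and PF4 at -2.87 ± 1.42). Hemoglobins and red cell proteins were lower in 20 of 20 (-0.73, with HBB at -0.73 ± 2.16) and heme synthesis and iron in 18 of 19 (-0.27, with the ferritin gene FTH1 at -0.37 ± 0.19). Smaller calls were G2 and M phase (19 of 20, -0.20, called higher without cycle 2 replicate 3), oxidative phosphorylation (20 of 21, -0.10), unfolded protein response (16 of 20, -0.18) and p53 and apoptosis (11 of 20, median -0.02, with GADD45B at -0.79 ± 0.27). These 10 lists beyond NF-kB had camera adjusted p of at most 0.0425. Their adjusted p were 0.359 to 0.759 with an estimated correlation. IL1B (-0.13 ± 0.29), the receptor genes IL1R1 (-0.98 ± 0.63) and IL1RAP (0.14 ± 0.79), and CD34 (0.13 ± 0.34) did not pass. Of 15878 genes edgeR called 0 (70 unadjusted). DESeq2 called 4, CXCL2, NFKBIA, DDIT4 and the erythroid gene RHEX, where RHEX was higher (0.90 ± 0.19) and the others lower.

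HSPC-like cells had lower NF-kB and immediate early genes at cycle 2, and NF-kB and TNF response was the 1 list of any cycle 2 comparison called with an estimated correlation too. It was lower in 17 of 20 genes with a median log2 change of -0.37 (camera adjusted p = 2.73e-22, and adjusted p = 0.0432 with an estimated correlation). By fry it was not called (adjusted p = 0.200), and without replicate 3 of both groups adjusted p was 0.633 with an estimated correlation. The class joins clusters whose shares differed widely between libraries, and these clusters were not tested apart. NFKBIA stood at 236 ± 78.0 CPM untreated and 104 ± 29.6 at cycle 2 (-1.16 ± 0.13), and CXCL8 at 15.1 ± 11.3 and 3.85 ± 3.73 (-2.17 ± 0.50). CXCL2 stood at 36.8 ± 44.5 and 11.4 ± 10.7 (-1.38 ± 0.27) and the early response gene IER3 at 5.97 ± 3.07 and 1.5 ± 0.732 (-2.04 ± 0.52). Each of these 4 was past the threshold adjusted over the list alone, and the untreated CXCL2 values vary by more than their mean. ID1, on chromosome 20 at 31605283 to 31606515, went from 74.5 ± 15.2 to 9.86 ± 1.14 CPM (-2.92 ± 0.22, edgeR adjusted p = 0.176). It stood at 57.6 to 87.1 CPM in untreated and 8.99 to 11.2 in cycle 2 libraries. Its relatives ID2 and ID3 stood at -1.27 ± 0.20 and -2.27 ± 0.61, and ID3 passed no threshold. The TGF-beta response list was lower in 15 of 16 (median -0.19, camera adjusted p = 3.72e-22, and adjusted p = 0.0556 with an estimated correlation).

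Immediate early genes were lower in 19 of 20 in HSPC-like cells (median -0.57), with ZFP36 at -1.25 ± 0.31, SOCS3 at -1.23 ± 0.31 and JUNB at -1.32 ± 0.39. Stem cell genes were lower in 18 of 20 (-0.21, with HLF at -0.38 ± 0.33) and unfolded protein response genes in 14 of 19 (-0.17, with the chaperone gene HSPA5 at -0.32 ± 0.16). Glycolysis and hypoxia genes were lower in 14 of 18 (-0.15, with DDIT4, an inhibitor of mTOR, at -0.72 ± 0.27). Myeloid transcription and granule genes were higher in 16 of 18 (0.39, with the granule protein gene AZU1 from 3.10 ± 2.43 to 11.8 ± 4.33 CPM). Erythroid transcription factors and signalling were higher in 14 of 17 (0.10, with the stem cell factor receptor gene KIT from 26.1 ± 3.63 to 44.1 ± 10.7 CPM, 0.73 ± 0.15). Cytotoxic effector genes, a list of other cell types, were higher in 4 of 5 (0.26, with CCL5 at 0.78 ± 0.28). These 7 lists had camera adjusted p of at most 0.0226. Their adjusted p were 0.142 to 0.232 with an estimated correlation. KIT passed adjusted over its list alone, as did ID1 in the stem cell list and ID1 and ID2 in the TGF-beta list. Of 12575 genes edgeR called 0 (91 unadjusted), and DESeq2 called 3, ID1, NFKBIA and ID2, each lower. Without the deposit block or without the expression filter edgeR called 1, ID1. Without the libraries that had the most cells over the mitochondrial limit (replicate 3 of both groups, a setting chosen after seeing the data) it called 63.

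Erythroid progenitor-like cells at cycle 2 had 44 genes that fell and 53 that rose of 11215 tested. These were 2 libraries against 2, since the other libraries had under 20 such cells. With 1 residual degree of freedom, the SE and p-values rest mostly on a spread shared over genes. They do not measure the spread of each gene between libraries. The genes that fell were led by the AP-1 and early response genes FOS (153 ± 124 to 29.4 ± 15.2 CPM, -2.33 ± 0.12, edgeR adjusted p = 3.34e-80), FOSB (-1.84 ± 0.16) and DUSP1 (-1.41 ± 0.13). JUN (-1.25 ± 0.12), JUNB (-0.75 ± 0.12) and IER2 (-0.60 ± 0.10) fell too, with the activation antigen CD69 (-1.14 ± 0.19), DDIT4 (-0.98 ± 0.18), PHTF1 (-0.96 ± 0.13) and NFKBIA (-0.80 ± 0.11). NR4A1 fell by 2.45, CXCL2 by 2.57, CXCL3 by 2.30, ID1 by 1.28 and NFKBIZ by 0.63 on the log2 scale. The genes that rose included the endogenous retroviral gene ERV3-1 (1.02 ± 0.18), the imprinted RNA MEG3 (0.97 ± 0.18) and the myeloperoxidase gene MPO (0.67 ± 0.18). Also among them were the splicing factor gene RNPC3 (0.66 ± 0.16), CRYGD (0.66 ± 0.18), the immunoproteasome gene PSMB9 (0.65 ± 0.15), C16orf54 (0.63 ± 0.18), FAM19A2 (0.62 ± 0.12) and THUMPD3-AS1 (0.62 ± 0.12). SPINK2, a stem cell marker, rose from 0.894 ± 0.113 to 7.5 ± 6.11 CPM. PRTN3 rose from 4.54 ± 1.06 to 8.78 ± 6.31 CPM, where the cycle 2 SD exceeds the rise.

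By list, immediate early genes were lower in 17 of 18 in erythroid progenitor-like cells (median -0.75, 10 genes fell) and NF-kB genes in 9 of 14 (-0.29, 4 fell). Unfolded protein response genes were lower in 15 of 19 (-0.21, with HSPA5 at -0.46 ± 0.08 and HSP90B1 at -0.35 ± 0.07), oxidative phosphorylation genes in 20 of 21 (-0.12, 0 fell), S phase in 16 of 20 (-0.16, 0 fell). Lower too were glycolysis and hypoxia in 10 of 17 (-0.16, 1 fell), TGF-beta response in 8 of 14 (-0.11, 2 fell) and plasma cell genes in 5 of 5 (-0.16, FKBP11 fell). Type I interferon genes were higher in 20 of 23 (0.21, where IFITM1 fell by 0.53). Interferon gamma genes were higher in 10 of 13 (0.15, 1 rose), myeloid genes in 8 of 12 (0.23, 2 rose) and stem cell genes in 12 of 14 (0.23, 2 rose and 1 fell). Adjusted over the list alone, 14 immediate early, 6 unfolded protein response and 4 NF-kB genes fell. Also adjusted over the list alone, 5 type I interferon, 4 interferon gamma and 5 myeloid genes rose. Camera adjusted p were at most 0.0383, and with an estimated correlation the 12 adjusted p were 0.512 to 0.593. HBB fell by 0.17, while GATA1 (0.03 ± 0.09), KLF1 (-0.11 ± 0.08), EPOR (0.07 ± 0.15), TFRC (0.00) and IL1B (-0.08 ± 0.10) did not pass. With 1 residual degree of freedom these calls depended on the settings. DESeq2 called 3 genes and a fit without the deposit block 0, a mitochondrial limit of 30% gave 6, and doublets kept or a finer clustering gave 28 or 26.

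In myeloid progenitor-like cells, also 2 libraries against 2, 5 genes fell and 0 rose of 9871 tested (358 unadjusted). They were CXCL8 (25.4 ± 14.4 to 4.46 ± 0.972 CPM, -2.35 ± 0.36, edgeR adjusted p = 5.27e-07), ID1 (-2.20 ± 0.40), JUNB (-0.98 ± 0.16), NFKBIA (-0.72 ± 0.16) and JUN (-0.68 ± 0.15). These SE and p-values too rest mostly on a spread shared over genes. NF-kB genes were lower in 12 of 15 (median -0.72, 7 adjusted over the list alone). The urokinase receptor gene PLAUR stood at -0.96 ± 0.27 and TNFAIP3, a brake on NF-kB, at -0.81 ± 0.29. Immediate early genes were lower in 15 of 18 (-0.37, with ZFP36 at -0.86 ± 0.22 and 7 adjusted over the list alone) and unfolded protein response genes in 16 of 19 (-0.24, with DDIT3 at -0.78 ± 0.30). Plasma cell genes were lower in 6 of 6 (-0.22, with DERL3 at -0.74 ± 0.24), stem cell genes in 7 of 11 (-0.13) and hemoglobins in 4 of 6 (-0.42). Camera adjusted p were at most 0.0413, and adjusted p with an estimated correlation were 0.752 for each of the 6 lists. DESeq2, a fit without the deposit block and a mitochondrial limit of 30% each called 0 genes. The receptor gene IL1RAP (0.10 ± 0.31), IL1B (0.14 ± 0.35), NLRP3 (0.36 ± 0.29) and CD34 (0.06 ± 0.22) did not pass.

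**Figure D3:**
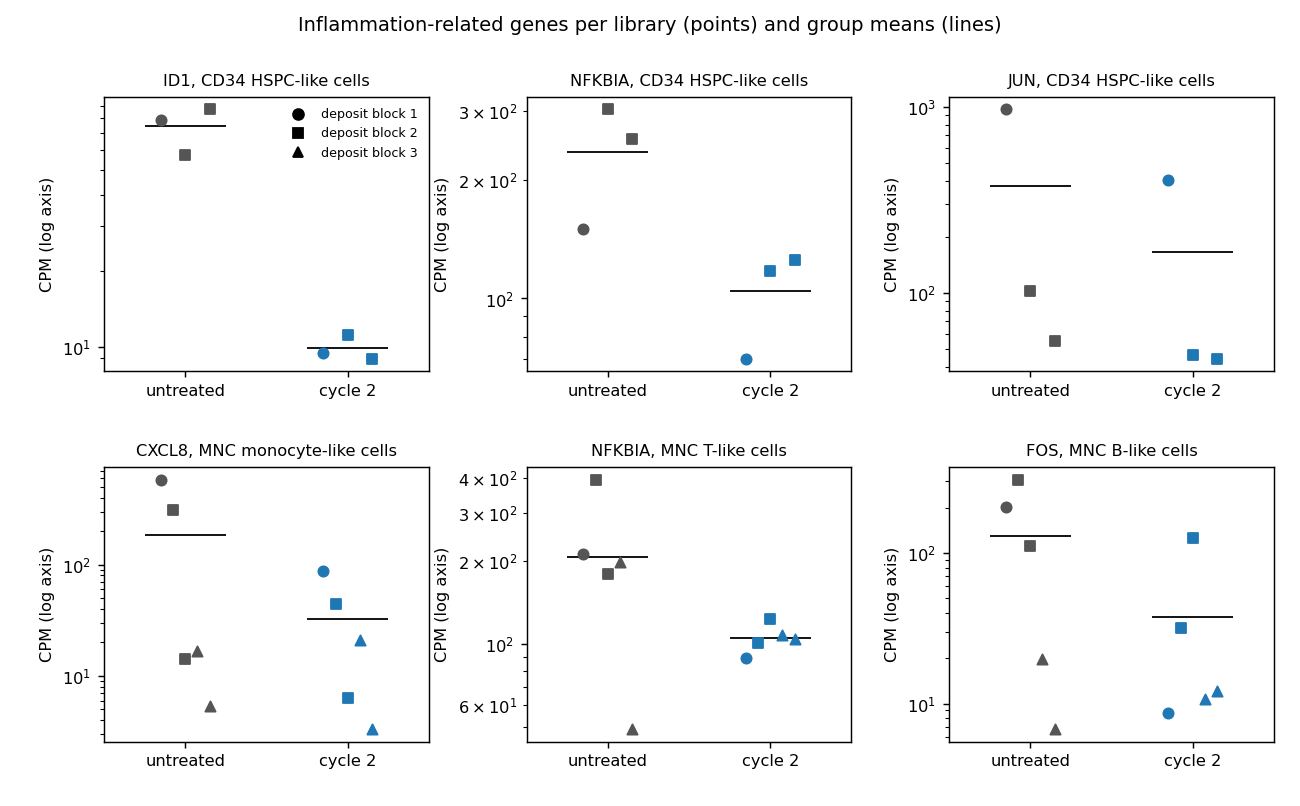
Expression of 6 gene and cell class pairs (CPM of the class in a library, log axis) in untreated and cycle 2 libraries, where each point is a library with its deposit block as symbol and each line is the group mean. ID1 in HSPC-like cells lies at 57.6 to 87.1 CPM in untreated and 8.99 to 11.2 CPM in cycle 2 libraries.

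Across the 10 cycle 2 comparisons, immediate early genes were called lower in 10 and NF-kB and TNF response genes in 9. With an estimated correlation 0 and 1 of these calls held, and the comparisons share libraries and cells, so they are not independent. The IL-1 pathway and inflammasome, IL-6 and STAT3 response, myeloid alarmin, T cell naive and memory and T cell inhibitory receptor lists were called in 0 of them. T cell inhibitory receptors were measured in 7 and the others in 10. With an estimated correlation the smallest adjusted p of these 5 lists were 0.548, 0.548, 0.611, 0.494 and 0.634.

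At later cycles, mononuclear cells compared within deposit block 1 showed higher platelet, MHC class II, myeloid alarmin and interferon genes. The platelet call alone held with an estimated correlation, the others having adjusted p of 0.0801 to 0.698, and without the block type I interferon genes were called lower. Platelet genes were higher in 12 of 14 with a median log2 change of 1.88, with a call by both correlations (camera adjusted p = 7.66e-17, adjusted p = 0.0119 with an estimated correlation, and fry adjusted p = 0.0302). Without the deposit block the platelet list was not called (camera adjusted p = 0.982, and adjusted p = 0.996 with an estimated correlation). PPBP (5.03 ± 0.84), PF4 (4.74 ± 0.85), the platelet receptor gene TREML1 (9.25 ± 2.36) and GNG11 (4.19 ± 1.10) were among 7 members past the threshold adjusted over the list alone. MHC class II genes were higher in 12 of 12 (median 1.10, 6 adjusted over the list alone), with HLA-DRA at 1.36 ± 0.37, HLA-DMA at 1.19 ± 0.32 and HLA-DPA1 at 1.30 ± 0.37. Myeloid alarmins were higher in 15 of 15 (3.14), with S100A8 at 4.64 ± 1.96, CD163 at 5.13 ± 1.77 and RETN at 4.07 ± 1.5. Myeloid transcription and granule genes were higher in 19 of 20 (1.96), with the macrophage receptor gene CSF1R at 4.28 ± 1.56 and CEBPE at 2.22 ± 0.79. Type I interferon genes were higher in 25 of 25 (0.86), with IFI44L at 1.48 ± 0.34 as the 1 member adjusted over the list alone. Interferon gamma genes were higher in 19 of 20 (0.62), IL-1 pathway and inflammasome genes in 21 of 23 (0.50, with NLRC4 at 3.61 ± 1.55) and plasma cell genes in 13 of 14 (0.85, with JCHAIN at 1.70 ± 0.73). NF-kB (20 of 24, 0.39), IL-6 and STAT3 (15 of 18, 0.48), hemoglobin (16 of 20, 0.84), glycolysis (16 of 20, 0.37) and T cell inhibitory receptor lists (13 of 14, 0.54) were higher and S phase genes (20 of 20, -0.44) lower. Within monocyte-like cells, compared after the data were seen, the NF-kB list was called lower, with CXCL8 at -2.85 ± 0.87. In B-like cells its members NFKB1 and TNF stood at -0.91 ± 0.30 and -1.52 ± 0.59. So the rise over all MNC was not seen within these classes.

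Beyond platelet genes, these 13 lists had camera adjusted p of at most 0.0357, and their adjusted p with an estimated correlation were 0.0801 to 0.698. All later libraries lie in block 1, so these changes are set against its 1 untreated library, which had 0.663% monocyte-like cells. Group means can differ in sign. PPBP stood at 99 ± 74.8 CPM over the 5 untreated and 45.9 ± 22.3 over the 5 later libraries. The megakaryocyte/platelet-like share was 0.211% in that untreated library, 1.29% over the 5 untreated and 0.476% over the 5 later libraries. Without the block, 4 of the 14 lists kept their call and direction, hemoglobins, myeloid, plasma cell and glycolysis genes. There 2 lists turned, with type I interferon genes called lower (camera adjusted p = 0.000207) and S phase genes higher (0.00163), and their adjusted p was 0.789 with an estimated correlation. IL1B (0.29 ± 0.87), CXCL8 (-0.27 ± 1.06), NFKBIA (0.52 ± 0.65), GATA1 (-0.05 ± 1.0), KLF1 (0.00) and HBB (2.53 ± 1.69) did not pass. Of 18420 genes edgeR called 0 (652 unadjusted, and 53 by DESeq2).

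CD34+ cells at later cycles showed lower stress, NF-kB and stem cell genes and higher myeloid genes, with adjusted p of 0.135 to 0.521 with an estimated correlation. They are set against the 1 untreated library of block 1, which had 53.3% HSPC-like and 3.11% myeloid progenitor-like cells. Immediate early genes were lower in 15 of 20 (median -0.39) with NR4A1 from 14.2 ± 6.67 to 4.98 ± 1.73 CPM (-2.13 ± 0.36) and JUNB from 136 ± 21 to 72.4 ± 16.4 CPM (-1.15 ± 0.25). IL-6 and STAT3 response genes were lower in 11 of 18 (-0.13) with SOCS3 at -2.08 ± 0.28 and BCL3 at -1.01 ± 0.21. NF-kB genes were lower in 17 of 23 (-0.35) with CXCL2 at -1.51 ± 0.37, the prostaglandin synthase gene PTGS2 at -1.20 ± 0.40 and CXCL3 at -1.06 ± 0.40. Stem cell genes were lower in 19 of 20 (-0.67), with the stem cell antigen gene THY1 at -1.38 ± 0.41, HOXA5 at -0.71 ± 0.23 and MLLT3 at -0.78 ± 0.34. TGF-beta response genes were lower in 13 of 20 (-0.16). Myeloid transcription and granule genes were higher in 19 of 20 (1.76), with MS4A3 from 12.3 ± 9.84 to 44.2 ± 6.50 CPM (2.16 ± 0.68), CEBPA at 0.77 ± 0.24 and CEBPE at 2.25 ± 0.87. Myeloid alarmins were higher in 12 of 15 (0.74) with TREM1 at 3.16 ± 0.82. Of these 7 lists, with camera adjusted p of at most 0.0388, the NF-kB, TGF-beta and myeloid transcription lists were also called the same way without the block, where adjusted p were at least 0.306 with an estimated correlation. Adjusted over the list alone, 5 immediate early genes, 2 of the IL-6 and STAT3 list and 1 of the TGF-beta list fell.

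Of the IL-1 system in CD34+ cells, IL1R1 stood at -1.80 ± 0.57, IL1RN, the natural receptor antagonist gene, at 1.46 ± 0.63, NLRP3 at 0.83 ± 0.29 and IL1B at -0.49 ± 0.26 at later cycles. The edgeR test called 0 of 16656 genes (675 unadjusted, and 59 by DESeq2). It called 192 without untreated replicate 2 and 178 without untreated replicate 3. HSPC-like cells formed 24.9% ± 8.62 of later CD34+ libraries, myeloid progenitor-like cells 14.7% ± 2.05 and megakaryocyte/platelet-like cells 16.6% ± 4.04.

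Across cycles 0 to 14 in deposit block 1, 0 of 11 MNC classes and 0 of 6 CD34+ classes followed the cycle number after adjustment. The MNC megakaryocyte/platelet-like share had Pearson's r = 0.845 (exact permutation p = 0.0185, adjusted p = 0.123, n = 7) and Spearman's rho = 0.786 (exact permutation p = 0.0480, adjusted p = 0.132). Its r was 0.792 without the 2 libraries farthest from the median cycle, cycles 11 and 14. Its shares were 0.211% untreated, 0.114% at cycle 2 and 0.357% to 0.633% at later cycles. The plasma-like share had r = 0.761 (exact permutation p = 0.0224, n = 7) and rho = 0.607, and the basophil/mast-like share r = 0.752 and rho = 0.857. The myeloid progenitor-like share had r = 0.730 and rho = 0.786, and the T-like share r = -0.650 and rho = -0.821 (adjusted p at least 0.123 by either measure). The plasma-like class held 832 cells here but 420 at Leiden resolution 2, where a lymphoid progenitor-like cluster of 440 cells stood apart. The myeloid progenitor-like class held 1261 cells here but 748 at resolution 2, where a conventional dendritic cell-like cluster of 522 stood apart. So these 2 classes may each mix cell types. Monocyte-like cells were 0.663% untreated, 3.70% at cycle 2, 7.63% at cycle 4, 7.57% at cycle 5, 13.1% at cycle 8, 2.60% at cycle 11 and 14.8% at cycle 14. Their share had r = 0.641 (exact permutation p = 0.126, adjusted p = 0.231, n = 7) and rho = 0.607. Without cycle 11, later replicate 4, 2 MNC classes passed. Without cycles 11 and 14, r was 0.993 for the monocyte-like, 0.960 for the myeloid progenitor-like and 0.922 for the basophil/mast-like share (exact permutation p of 0.00833 to 0.0167, n = 5, not adjusted). It was 0.555 for the plasma-like and -0.410 for the T-like share. In CD34+ libraries the r values lay between -0.342 and 0.367 (smallest exact permutation p = 0.409, n = 7, adjusted p at least 0.892). Without cycles 11 and 14 the HSPC-like share had r = -0.939 (exact permutation p = 0.0250, n = 5, not adjusted).

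**Figure D4:**
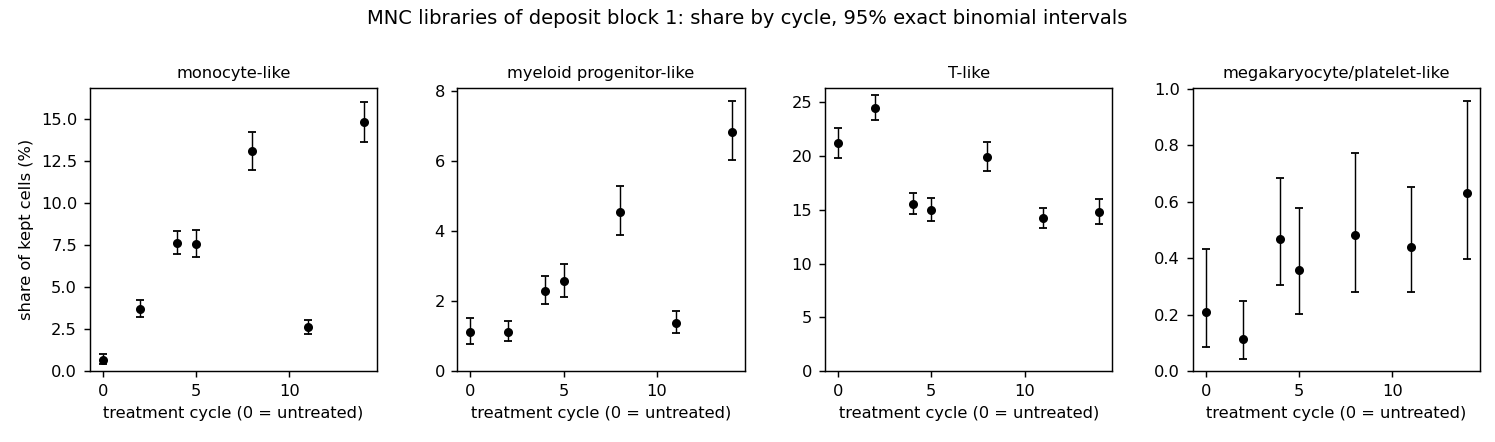
Share of kept cells (%, vertical axis) in 4 classes of the 7 MNC libraries of deposit block 1 against treatment cycle (horizontal axis, 0 is untreated). Points are libraries and bars are exact 95% binomial intervals, with monocyte-like cells at 0.663% untreated and 14.8% at cycle 14.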

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

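All tests of explanations in this part, the splits of the libraries included, were chosen after the results were seen.

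NF-kB and TNF response genes were called lower in 9 and immediate early genes in 10 of the 10 cycle 2 comparisons. These comparisons share libraries and cells, and with an estimated correlation 1 and 0 of the calls held. Without the libraries with the most cells over the mitochondrial limit, 6 of the 6 comparisons that could be refitted still called the NF-kB list lower (camera adjusted p at most 0.0324, and adjusted p = 0.258 to 0.969 with an estimated correlation). So the camera calls did not need these libraries. Such calls also came from other splits of the libraries, given below, so this does not settle their source. With an estimated correlation 5 of the 6 were not called with these libraries in either, so that test decides nothing about them. Free RNA from monocyte-like cells could bring at most 1.303% of these lists' CPM in T-like or B-like cells of any library. In these cells the summed CPM of the lists was not lower at cycle 2 in deposit block 3. Lower IL-1 beta signalling under canakinumab stays open beside handling stress that differed between the groups. Handling was not tested, since the labels give no measure of it and the immediate early genes that respond to it are part of the pattern. The call that held with an estimated correlation was that of HSPC-like cells. Without the libraries above, 2 libraries against 2, its camera adjusted p was 3.47e-27, and adjusted p = 0.633 with an estimated correlation.

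Other splits of the same libraries bear on these calls. The splits move libraries across deposit blocks, and each fit keeps the block as a covariate. For the p of the NF-kB list, 7 of 60 splits gave one as small in all MNC (real 0.0002646, lowest other 6.709e-08), 11 of 100 in monocyte-like (7.24e-09, 5.353e-15), 12 of 100 in T-like (0.0004056, 1.275e-09), 7 of 100 in B-like (4.365e-07, 2.114e-11) and 4 of 34 in erythroid-like cells (0.0005045, 9.411e-06), so chance was not excluded. The 10 splits of the CD34+ libraries are too few for a share under 0.05: the real p was 1.051e-09 and the lowest other 0.000661 over all cells (1 of 10), and 2.1e-23 and 2.509e-05 in HSPC-like cells (1 of 10). For the number of lists called at cycle 2, as many came from 48 of 60 splits in all MNC (10, highest other 19), 59 of 100 in monocyte-like (5, 11), 70 in T-like (6, 16), 84 in cytotoxic T/NK-like (4, 15), 68 in B-like (5, 14) and 31 of 34 in erythroid-like cells (4, 12), so chance was not excluded. In CD34+ cells 4 of 10 splits gave as many over all cells (11, highest other 14) and 3 of 10 in HSPC-like cells (9, highest other 11), too few splits for a share under 0.05.

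Genes called were 0 in the real cycle 2 split of each MNC comparison, a count that every split reaches, so these splits test nothing about it: 60 of 60 over all MNC, 100 of 100 in monocyte-like, T-like, cytotoxic T/NK-like and B-like cells each, and 34 of 34 in erythroid-like cells. The highest other splits called 6380 genes in all MNC, 852 in monocyte-like, 2461 in T-like, 583 in cytotoxic T/NK-like, 113 in B-like and 919 in erythroid-like cells, which points to a structure of these libraries whose source was not tested. In CD34+ libraries 10 of 10 splits gave as many as the real 0, with highest others of 0 over all cells and 7 in HSPC-like cells. The same holds at later cycles for the real 0 genes, with 60 of 60 splits of MNC (highest other 21) and 56 of 56 of CD34+ libraries (highest other 1). As many lists were called at later cycles in 22 of 60 splits of MNC (14, highest other 20) and 45 of 56 of CD34+ libraries (7, highest other 15), so chance was not excluded for the lists.

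The gene lists called at later cycles in MNC may come from the single untreated library of the later libraries' block: without the block, 4 of 14 lists were still called the same way, 2 turned and the platelet list was not called. A larger share of monocyte-like cells stays open for the myeloid alarmins, whose median was 3.14 over all MNC and 0.7729 within monocyte-like cells, where they were not called. They were called higher within the other 4 MNC classes (camera adjusted p at most 0.000263, and adjusted p = 0.0861 to 0.371 with an estimated correlation). Free RNA from monocyte-like cells could carry these calls and was not tested at later cycles. The make-up of a class can also differ between the groups. For example, 1 erythroid-like cluster held a mean of 5.51% of later and 0.053% of untreated MNC. The MHC class II list was called higher within 3 of 5 MNC classes, with a median of 1.08 within monocyte-like cells and 1.10 over all MNC. The median of 1.08 rests on 22 monocyte-like cells of the block's 1 untreated library, and free RNA was not tested for this list. So a larger share stays open here too. Adjusted p with an estimated correlation were 0.535 in monocyte-like, 0.736 in T-like and 0.672 in B-like cells, but 0.128 over all MNC too, so that test decides nothing about the share. The block and the later cycles cannot be told apart in these libraries beyond that 1 untreated library.

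In CD34+ libraries at cycle 2, a shift between the named cell classes stays open for the lower platelet and hemoglobin lists, which 1 of 5 tests within classes called lower. These tests did not cover megakaryocyte/platelet-like or erythroid-like CD34+ cells, so they cannot decide it. Megakaryocyte/platelet-like cells formed 7.58% ± 2.19 of untreated and 6.16% ± 3.37 of cycle 2 cells, and erythroid-like cells 10.4% ± 9.66 and 6.36% ± 6.80. The higher myeloid list was called within classes in 2 of 3 tests, with a median of 0.39 in HSPC-like and 0.23 in erythroid progenitor-like cells and 0.56 over all CD34+ cells. Adjusted p were 0.204 and 0.535 in these classes and 0.485 over all cells with an estimated correlation, so a shift stays open for part of it.

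A library stood far from the others of its group in 15 of 130 groups of values, against about 6.5 by chance. In MNC these were an HSPC-like share of 11.8% in cycle 2 replicate 4, a basophil/mast-like share of 1.592% and a monocyte-like share of 9.502% in cycle 2 replicate 3, a T-like share of 19.94% in later replicate 3, a plasma-like share of 2.617% in later replicate 5 and an HSPC-like share of 17.49% in untreated replicate 4, which also had CD34 at 58.98 CPM. In untreated MNC replicate 3, 61% of barcodes exceeded the mitochondrial limit, NLRP3 stood at 29.59 CPM and TNFAIP3 at 179 CPM, and in cycle 2 replicate 3 TNFAIP3 stood at 121.8 CPM. The decoy receptor gene IL1R2 stood at 3.683 CPM in untreated MNC replicate 5 and at 8.921 CPM in later MNC replicate 5. In later CD34+ replicate 4, S100A8 stood at 46.11 CPM and S100A9 at 60.07 CPM.

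The cycle 2 change differed between CD34+ and MNC libraries for 9 lists by camera over 16 libraries, of which 0 held with an estimated correlation (smallest adjusted p = 0.236). Of the 16 libraries, 12 come from 6 marrows measured in both fractions, and the fit did not account for the shared marrow. The median difference of the log2 change, CD34+ minus MNC, was 0.3025 for type I interferon, 0.289 for interferon gamma, 0.5428 for myeloid transcription and granule, -1.193 for hemoglobin, -0.4479 for heme synthesis, -0.1877 for stem cell, -0.3353 for G2 and M phase, -0.1582 for TGF-beta response and -1.005 for platelet genes. The edgeR test called 0 of 18139 genes for the difference (65 at an unadjusted p under 0.05). DESeq2 was not run on this difference.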

How the results depend on the processing

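The mitochondrial limit of 30% and the fits without the libraries with the most cells over the limit were chosen after seeing the data. No paired analysis was possible because the labels do not give donors across treatment groups and the replicate numbers only name libraries. The 2 fractions of a marrow were paired for the CD34 transcript alone. Of values for named genes, 985 of 1181 kept their sign and whether they were called when a library was left out. Under other alternatives 1352 of 1585 did, where 146 lost their call. The values with a library left out held no gene called in the main fit, so there uncalled genes stayed uncalled. Gene values not called in the main fit changed sign in 196 and 81 cases. Of class shares and trends, 234 of 265 and 217 of 230 kept both, and 29 and 13 changed sign. Of counts of calls, which have no sign, 139 of 142 and 120 of 145 stayed close to the main count. Values called in the main fit changed sign in 0 cases, but called lists turned: type I interferon and S phase in later MNC without the deposit block, and G2 and M phase in CD34+ cells at cycle 2 without cycle 2 replicate 3. DESeq2 called 53 genes for later MNC (51 higher, 2 lower), 59 for later CD34+ cells (53 higher, 6 lower), 4 for cycle 2 CD34+ cells, 3 for HSPC-like, 3 for erythroid progenitor-like (FOS, JUN and DUSP1), 1 for erythroid-like and 0 for myeloid progenitor-like cells. Without the expression filter edgeR called 19 genes in monocyte-like, 15 in cytotoxic T/NK-like, 14 in B-like, 13 in erythroid-like, 3 in T-like (CLC higher, FOS and IFI27 lower), 1 in HSPC-like (ID1) and 3 in myeloid progenitor-like cells (CXCL8, ID1 and JUNB), names chosen after their values were seen. Without the deposit block it called 1 in HSPC-like (ID1), 0 in erythroid progenitor-like and 0 in myeloid progenitor-like cells. Erythroid progenitor-like cells gave 28 genes with doublets kept, 26 at Leiden resolution 2 and 6 at a mitochondrial limit of 30%, where myeloid progenitor-like cells gave 0. Without the libraries with the most cells over the limit, HSPC-like cells gave 63 genes (13 higher, 50 lower) and later CD34+ cells 178. With each library left out in turn, later CD34+ cells gave 0 to 192 genes, with 192 without untreated replicate 2 and 178 without untreated replicate 3, and MNC shares by cycle gave 0 to 2 classes, with 2 without later replicate 4. The fits that gave 192 and 178 genes take their spread from the later libraries alone. Of the 93 list calls, 2 held with an estimated correlation and 1 with fry. The other settings called 80 to 112 lists, newly called ones included, and of the 93 calls 66 were kept without the deposit block and 75 without the expression filter. The causes were not tested. No library could be left out of the erythroid progenitor-like and myeloid progenitor-like fits, which have 2 libraries per group. Over all CD34+ cells at cycle 2, 0% of simulated 4-fold changes were recovered, so the edgeR test called no gene changes of that size there, while DESeq2, which was not simulated, called 4 genes in the libraries. HSPC-like cells of the same libraries recovered 61% from fewer cells, so depth alone does not set this limit.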

Other observations

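Class comparisons at later cycles were added after the data were seen, and so were the genes named in this part. In monocyte-like cells at later cycles NF-kB genes were lower in 21 of 24 (median -0.79), with CXCL8 at -2.85 ± 0.87 and CCL3 at -2.02 ± 0.55, and cytotoxic effector genes in 16 of 18 (-0.94). Type I interferon genes were higher in 24 of 25 (1.18, with BST2, which tethers virions to cells, at 1.59 ± 0.42 and ISG15 at 2.14 ± 0.75), MHC class II genes in 10 of 12 (1.08, with HLA-DPA1 at 1.74 ± 0.39), ribosomal protein genes in 25 of 25 (1.15) and oxidative phosphorylation genes in 21 of 21 (1.02). The camera adjusted p were at most 0.000191, and adjusted p was 0.535 with an estimated correlation for each of these 6 lists. The edgeR test called 3 genes of 12026, each lower: NABP1 (-1.89 ± 0.26), CCR6 (-8.70 ± 1.14) and CCL4L2 (-4.52 ± 0.63), at adjusted p = 0.0468. The untreated library of the same block, which these folds rest on, had 22 monocyte-like cells.

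HSPC-like CD34+ cells at later cycles had lower immediate early genes (18 of 20, median -0.68), NF-kB genes (18 of 21, -0.38), stem cell genes (18 of 20, -0.30) and IL-6 and STAT3 response genes (11 of 17, -0.26), and higher S phase genes (20 of 20, 0.54) and myeloid genes (16 of 18, 0.38). The camera adjusted p were at most 0.000235, and adjusted p were 0.0639 to 0.560 with an estimated correlation. The edgeR test called 0 of 12632 genes (283 at an unadjusted p under 0.05). DESeq2 was not run for classes at later cycles. In erythroid progenitor-like cells edgeR called 5 of 11968 at adjusted p = 0.0418, where the galectin gene LGALS1 rose (0.89 ± 0.16) and the heat shock gene HSPA1A (-0.99 ± 0.18), the nuclear receptor gene NR4A1 (-1.55 ± 0.27), ID1 (-1.05 ± 0.19) and ZNF331 (-0.99 ± 0.18) fell. These comparisons are set against 1 untreated library of the same block.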
